A study of Mus musculus with 3 samples.

How the data were processed

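Sorted cells of the embryonic mouse kidney were profiled on 3 one-colour oligonucleotide arrays, all of 1 group. Per the labels, the mice carried a Mafb-EGFP transgene, a green fluorescent reporter driven by regulatory sequence of Mafb, on the outbred CD-1 strain. Mafb encodes a transcription factor made by podocytes, the epithelial cells that wrap the glomerular capillaries, and also by macrophages. Kidneys were taken at E15.5 (E, embryonic day; Theiler stage 23) and dissociated with trypsin for 5 minutes. GFP-positive cells were collected by fluorescence-activated cell sorting (FACS), which separates single cells by their fluorescence. Each array received RNA from a pool of about 5 to 10 kidneys. Per the labels' protocols, total RNA went through 2 rounds of amplification and was labelled with biotin. No label says which litters or sorts the pools came from, so the p-values measure the spread between these arrays, which may be partly technical. No GFP-negative or unsorted kidney sample was analysed here, and a signal level is therefore no measure of enrichment by the sort.

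The deposited values were linear intensity values, 1 per probe set and array, where a probe set is the group of short probes designed for a transcript. GCOS, the array maker's software, is named in the submitters' processing notes, without a version. The summary algorithm and the scaling target are not given in the sources used here. In the values, the 2% trimmed mean was 1499.55, 1499.51 and 1499.56 on arrays 1, 2 and 3, as scaling each array to a common level gives. The values were used as deposited, without further normalization, and log2 was taken with no pseudocount.

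Of 45101 probe sets, 64 were control probe sets and 45037 were tested. Gene names came from the platform's annotation table, with symbols updated by gene ID through a RefSeq table of the mouse assembly GRCm38.p6, which matched 99.4% of the gene entries. There 34945 probe sets had 1 symbol and 932 had several, and 9160 were not listed. These gave 18193 genes, of which 9183 had 1 probe set. No gene was named from a probe set with several symbols, and no coordinates are given, because the values name no genome build. Mafb itself and Nphs2, which encodes podocin, were not analysed here, since neither had a probe set of a single symbol.

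The background level of an array was the 95th percentile of 126 probe sets for olfactory, vomeronasal and bitter taste receptors and keratin-associated proteins. It came to 207 on array 1 (95% bootstrap interval 145 to 225), 176 on array 2 (157 to 236) and 147 on array 3 (119 to 227), from 2000 draws. Each log2 signal minus its array's level was fitted with an intercept in limma 3.58.1 under R 4.3.3, with moderated variances that follow the signal. The test was one-sided, for signal above background, with Benjamini-Hochberg adjustment over the 45037 probe sets. A probe set was called at an adjusted p below 0.05. The test takes each array's background level as known, so calls close to it do not carry the uncertainty of that level. A gene was represented by its probe set of highest mean signal. Signals of different genes come from different probes and do not rank their transcripts by abundance.

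Gene lists for podocytes, other kidney cell types and cell states were fixed before the data were examined, as were the test, the background list, the rule for named genes and all alternatives but those said to be added. The ribosomal list took symbols beginning with Rpl or Rps, without kinases and pseudogenes. The share of called members and the median signal of a list were set against 10000 random gene lists matched on the number of probe sets per gene. For differences between arrays, each gene's deviation from its mean over the 3 arrays was taken, relative to the array's median gene. The median over called members was set against 10000 random lists matched on mean signal in 20 bins. These percentiles describe these arrays and are no p-values, since genes of a list vary together. Named genes were a fixed panel, the 3 called members of highest signal and the 2 uncalled members of lowest signal in each list, the 10 non-ribosomal genes of highest signal, and the 10 called genes with the largest range between arrays.

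The procedure was tested on simulated data with the 45037 probe sets. For genes above background, 50 probe sets in each of 10 runs were placed at a known level. Of those at 0, 1, 2 and 3 above background (log2), 1%, 83.8%, 100% and 100% were called. For the list shift on array 3, lists of 16 genes shifted by 0, 0.3 and 0.5 gave mean estimates of -0.01, 0.29 and 0.49. They lay above the 97.5th percentile in 0, 10 and 10 of 10 runs. The simulated noise was independent, with the same SD for all probe sets of a given signal, and the lists were random genes. The rates therefore do not carry over to probe sets of wider spread or to lists whose genes vary together.

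The alternatives were quantile normalization, a pseudocount of 16, background at the 90th or 99th percentile or at the 40th percentile of all probe sets, the mean over a gene's probe sets, leaving out probe sets that can match several transcripts (suffixes _s_at, _x_at and _a_at), variances without the trend, a call on all 3 arrays with no test, no filter on dim probe sets, and each array left out in turn. A background list without keratin-associated proteins was added after the data were seen, as was the recomputing of the list shifts under other settings. The number of arrays limits the precision of every value.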

Results

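Gene expression was measured in GFP-positive cells sorted from kidneys of Mafb-EGFP mice at E15.5 (E, embryonic day), in 3 pools with 1 Affymetrix whole-genome mouse array each. All 3 arrays form 1 group, so the design asks which transcripts the sorted cells contain and how much the pools differ. Levels are given as the log2 signal above the background level of the same array, as mean ± SD over n = 3 arrays, with adjusted p-values from limma. Above background lay 10599 of 18193 genes (58.3%), and 3141 of them by more than 5 on the log2 scale. Of 45037 probe sets 18761 were called (41.7%). Of the 126 background probe sets 2 were called (1.59%), but the background level was set near the top of these same probe sets. By construction few of them could be called, so this share is no independent rate of false calls. The median signal was 192, 180 and 191 on arrays 1, 2 and 3. Across the called probe sets the log2 signals correlated with Pearson's r of 0.962 between arrays 1 and 2, 0.9503 between arrays 1 and 3, and 0.942 between arrays 2 and 3. Over all probe sets r was 0.9199, 0.9274 and 0.9167 for the same pairs, so which pair was most alike depended on the probe sets taken. Probe sets are not independent replicates. The median SD of the called genes was 0.26. The ratio of 3' to 5' signal, which grows as transcripts are shortened, was 7.63, 9.11 and 7.14 for the actin control and 26.0, 26.9 and 23.9 for the Gapdh control on arrays 1, 2 and 3.

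Most genes of the podocyte programme gave signal above background. Of 54 measured members of the 4 podocyte lists, 48 (88.9%) were above background. The share was 94.1% for the endothelial, stromal and macrophage lists and 91.7% for ribosomal proteins. A high share of calls therefore does not by itself single out podocytes. All 7 measured transcription factors were called. Wt1, the Wilms tumour suppressor required for podocyte differentiation, stood at 6.58 ± 0.74 (adjusted p = 4.08e-08). Dach1 reached 6.46 ± 0.43 and Tcf21, a factor needed for glomerular development, 5.73 ± 0.34. Lmx1b, mutated in nail-patella syndrome, stood at 1.83 ± 0.33 (adjusted p = 0.000115), but the mean over its 2 probe sets was 0.44 and not called (adjusted p = 0.257, and 2.22e-05 to 0.257 over 13 alternatives). The share of called transcription factors lay at the 99.1th percentile of matched random lists and their median signal, 5.23, at the 99.3th.

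Of the slit diaphragm and junction list, the proteins of the filtration slit between podocyte processes, 13 of 15 members were called (97.6th percentile). Nphs1, which encodes nephrin, was 1.91 ± 0.58 above background (adjusted p = 0.000201). The junction and polarity genes Fat1 (7.57 ± 0.33), Tjp1 (7.21 ± 0.47) and Prkci (7.20 ± 0.26) had the highest signals of the list. The call of Prkci rested on a probe set that can match several transcripts, with -0.13 without it. Kirrel3 (-0.83 ± 1.11) and the channel gene Trpc6 (-2.45 ± 2.90) were not called. Among foot process and surface proteins 16 of 18 were called (98.4th percentile). Vim (8.05 ± 0.24), the aminopeptidase gene Enpep (7.83 ± 0.37) and Podxl, which encodes the apical sialoprotein podocalyxin (7.80 ± 0.33), led the list. Synpo, the gene of the actin-associated protein synaptopodin, stood at 5.07 ± 0.40 (adjusted p = 3.57e-08). Tns2 (0.84 ± 0.97, adjusted p = 0.0772) and Rhpn1 (0.42 ± 2.05, adjusted p = 0.573) were not called over all 3 arrays, but both were called without array 3, at 1.39 (adjusted p = 0.000812) and 1.60 (adjusted p = 0.000209); over 13 alternatives their adjusted p reached 1. Adjusted over the list alone, the counts were 7 for transcription factors, 13 for the slit diaphragm and 17 for foot processes.

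Secreted factors and receptors described in podocytes were called in 12 of 14 cases, and in 12 adjusted over the list alone, a share within the range of random lists (86.9th percentile). Efnb2 (6.81 ± 0.41), the integrin ligand gene Npnt (5.73 ± 0.15) and the chemokine gene Cxcl12 (5.54 ± 0.87) had the highest signals. Vegfa, the endothelial growth factor secreted by podocytes, stood at 3.47 ± 0.56 (adjusted p = 1.35e-06). Fgf1 (0.44 ± 1.25) and Robo2 (-1.67 ± 0.93) were not called.

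Basement membrane genes were called in 18 of 19 cases (99.7th percentile; 18 adjusted over the list alone). Lamb1 (7.76 ± 0.21), Col4a1 (7.37 ± 0.26) and Nid1 (6.67 ± 0.43) led the list. Lamb2, the laminin chain of the mature glomerular basement membrane, was 2.88 ± 0.12 above background (adjusted p = 1.13e-06). The collagen IV chains of the mature membrane gave a mixed picture. Col4a4 was called at 1.68 ± 0.72 (adjusted p = 0.000958) on 1 of its 3 probe sets, and stood at -1.13 as the mean over them. Col4a3 was the uncalled member, at -0.72 ± 2.94, with signals of 208, 612 and 9.56 on arrays 1, 2 and 3. Of the genes mutated in human nephrotic syndrome or focal segmental glomerulosclerosis, 24 of 28 were called (99.9th percentile; 25 adjusted over the list alone), led by Ptpro (7.04 ± 0.63) and Scarb2 (7.001 ± 0.207). Of the 28 measured genes, 12 also stood on the podocyte lists. Coq8b (-0.39 ± 0.14) was not called.

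**Figure D1:**
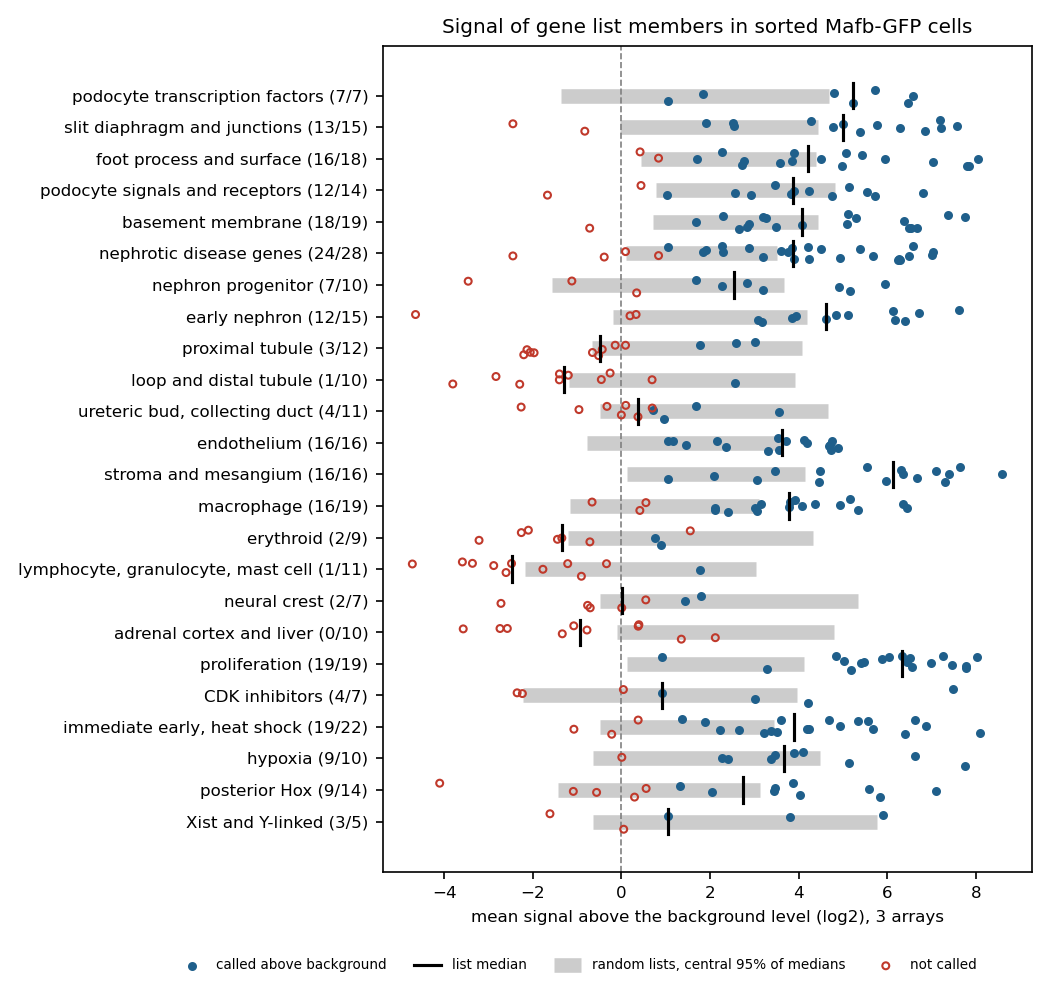
Mean signal above the background level (log2, horizontal axis) over 3 arrays for each measured member of the fixed gene lists (rows, with called and measured members in brackets); filled points were called, open points were not, black bars are list medians and grey bars the central 95% of medians of random lists. Podocyte transcription factors (median 5.23), stroma (6.14) and macrophage genes (3.79) lie above their grey bars, and the liver and adrenal list (median -0.92) lies below.

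Genes of earlier nephron stages were also present. Of the renal vesicle and S-shaped body list, the structures from which podocytes arise, 12 of 15 were called, a share at the 91.2th percentile, and the median of 4.61 lay at the 99.3th. The cyclin gene Ccnd1 (7.63 ± 0.06), the Notch ligand gene Jag1 (6.72 ± 0.13) and the Notch target Hey1 (6.40 ± 0.18) led it, while Lfng (0.20 ± 0.47) and Fgf8 (-4.644 ± 1.495) were not called. Nephron progenitor genes were called in 7 of 10 cases (90.2th percentile). Itga8 (5.95 ± 0.83), Sall1 (5.17 ± 0.44) and Eya1 (4.92 ± 0.59) were high on their brightest probe sets, and Six2, the factor that maintains progenitors, was called at 1.69 ± 0.71 (adjusted p = 0.000867). The mean over the 3 probe sets of Eya1 was 0.18 and not called (adjusted p = 0.74, the highest of 13 alternatives, with 1.34e-37 the lowest). Cited1 (-3.46 ± 1.30) and Osr1 (-1.12 ± 0.34) were not called. Adjusted over the list alone, 12 and 7 members were called.

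Most markers of differentiated tubules were not called above background. Of 33 measured members of the proximal tubule, loop and distal tubule, and ureteric lists, 8 (24.2%) were called. No unsorted kidney was analysed here. The share does not show whether the sort removed tubule cells or the whole kidney at E15.5 gives as few calls. For the proximal tubule 3 of 12 were called (0.46th percentile): Hnf4a (3.01 ± 0.42), Aqp1 (2.59 ± 0.44) and the megalin gene Lrp2 (1.78 ± 0.76). The call of Hnf4a rested on a probe set that can match several transcripts, with -0.71 without it. The transporter genes Slc22a8 (-2.13 ± 0.76) and Slc22a6 (-2.20 ± 1.16) were not called. For the loop and distal tubule 1 of 10 was called (0.14th percentile), Pou3f3 (2.58 ± 0.97), and Cldn19 (-2.83 ± 1.01) and Slc12a3 (-3.80 ± 0.75) were not. Without array 3 the count was 2, and with the mean over its probe sets Pou3f3 was 0.20 and not called (adjusted p = 0.7, the highest of 13 alternatives, with 4.27e-16 the lowest). For the ureteric bud and collecting duct 4 of 11 were called (2.08th percentile), among them Calb1 (3.56 ± 1.15), Wnt11 (1.69 ± 0.17) and Gata3 (0.97 ± 0.42). Without array 3 the count was 2, and Gata3 was no longer called (0.73, adjusted p = 0.0563), nor with background at the 99th percentile (0.13, adjusted p = 0.895; 0.000418 to 0.895 over 13 alternatives). The mean over the probe sets of Calb1 was -0.26. Aqp3 (-0.96 ± 0.95) and Elf5 (-2.26 ± 1.03) were not called. Adjusted over the list alone, the counts were 3, 1 and 3.

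Marker genes of stroma, endothelium and macrophages were above background, in 48 of 51 cases (94.1%). All 16 measured stromal and mesangial genes were called, with a median of 6.14 at the 100th percentile. The fibrillar collagen genes Col3a1 (8.60 ± 0.21) and Col1a2 (7.39 ± 0.63) and the smooth muscle actin gene Acta2 (7.64 ± 0.27) led the list, and the stromal progenitor factor Foxd1 stood at 4.45 ± 0.33 (adjusted p = 6.2e-08). Acta2 was -0.16 without the probe sets that can match several transcripts. All 16 endothelial genes were called (100th percentile), among them Cdh5 (4.89 ± 0.67), Sox17 (4.76 ± 0.58) and the angiopoietin receptor gene Tek (4.72 ± 1.48). Of the macrophage genes 16 of 19 were called (99.9th percentile), with Csf1r, the receptor for colony-stimulating factor 1, at 6.44 ± 0.31 (adjusted p = 9.28e-09). Ctss (6.37 ± 0.50), Mrc1 (5.35 ± 1.07), Adgre1 (4.36 ± 1.02) and C1qa (3.06 ± 0.30) were also called, and Aif1 (0.42 ± 0.63) and Cd163 (-0.66 ± 0.37) were not. Adjusted over the list alone, the counts were 16, 16 and 16.

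Other blood, nerve and neighbouring organ markers gave 5 calls among 37 members (13.5%). The erythroid list had 2 of 9 (1.49th percentile), Slc4a1 (0.90 ± 0.86, adjusted p = 0.0498) and Alas2 (0.76 ± 0.17, adjusted p = 0.0361), and limma gave 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. Neither was called without array 2, at 0.66 (adjusted p = 0.195) and 0.68 (adjusted p = 0.181); without array 3 Slc4a1, at 0.64 (adjusted p = 0.18), was not called, and without array 1 Alas2, at 0.76 (adjusted p = 0.119), was not. Slc4a1 lost its call under 8 of 13 alternatives (adjusted p from 0.00257 to 1) and Alas2 under 3 of 12 (0.00174 to 1). The globin gene Hbb-bh1 (-2.26 ± 1.36) and Epb42 (-3.21 ± 1.49) were not called. The lymphocyte and granulocyte list had 1 of 11 (0.98th percentile), Cd79b (1.78 ± 0.32), with Cd3e (-3.59 ± 0.35) and S100a9 (-4.72 ± 0.36) below background. The neural crest list had 2 of 7 (1.15th percentile), Dbh (1.80 ± 0.36) and Elavl4 (1.43 ± 1.35), the latter not called without array 3 (0.71, adjusted p = 0.1), which left a count of 1. Elavl4 lost its call under 4 of 13 alternatives (adjusted p from 0.000441 to 0.634). Dbh rested on a probe set that can match several transcripts, and was not called without it (0.12, adjusted p = 0.822) or with the mean over its probe sets (0.01; adjusted p from 1.1e-05 to 1 over 13 alternatives). Prph (-0.76 ± 0.44) and Tubb3 (-2.72 ± 0.57) were not called. None of the 10 adrenal cortex and liver genes was called by limma (0th percentile; 0 also adjusted over the list alone, and 1 at an unadjusted p under 0.05), with Ahsg at -2.74 ± 2.16 and Apoa1 at -3.57 ± 2.02; without array 2 the count was 2. Adjusted over the list alone, the lymphocyte and neural crest counts were 1 and 2.

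The sorted cells gave strong cell cycle signals. All 19 measured genes of S phase and mitosis were called (100th percentile; 19 adjusted over the list alone), with Rrm2 at 8.02 ± 0.23, Top2a at 7.78 ± 0.20, Pcna at 7.77 ± 0.18 and the proliferation marker Mki67 at 7.25 ± 0.14. Of the cyclin-dependent kinase inhibitors, which arrest the cycle, 4 of 7 were called (67.5th percentile; 4 adjusted over the list alone). Cdkn1c, which encodes p57 and marks podocytes that leave the cycle, stood at 7.47 ± 0.30 (adjusted p = 7.89e-09), Cdkn2c at 4.22 ± 0.44 and Cdkn2d at 3.02 ± 0.18. Cdkn2b (-2.23 ± 1.68) and Cdkn2a (-2.35 ± 0.90) were not called. A pool of cells does not show whether the same cells carried both sets.

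Genes that tissue dissociation can induce were above background in 19 of 22 cases (99.9th percentile; 19 adjusted over the list alone). Hsp90aa1 (8.10 ± 0.17), Egr1 (6.87 ± 0.40) and Fos (6.62 ± 0.43) were high, and Fosb (-0.22 ± 0.72) and Junb (-1.07 ± 0.90) were not called. Of the genes induced by low oxygen 9 of 10 were called (97.4th percentile; 9 adjusted over the list alone), with the glycolytic genes Pgk1 (7.76 ± 0.31) and Ldha (6.63 ± 0.54) and the mitophagy gene Bnip3 (5.13 ± 0.82) highest and Car9 (0.01 ± 0.53) not called. Posterior Hox genes, which are active in the posterior trunk, the kidney included, were called in 9 of 14 cases (88.6th percentile; 9 adjusted over the list alone). Hoxa9 (7.10 ± 0.40), Hoxd10 (5.83 ± 0.44) and Hoxa10 (5.60 ± 0.62) led, and Hoxa13 (-1.08 ± 0.45) and Hoxd12 (-4.10 ± 1.18) were not called. Both Xist, the RNA that silences an X chromosome in female cells (5.91 ± 1.05), and the Y-linked Eif2s3y (3.81 ± 0.03) were called. Of this list 3 of 5 were called (26.9th percentile; 3 adjusted over the list alone), including Kdm5d (1.05 ± 0.39), which was not called without array 1 (0.92, adjusted p = 0.074) and had a mean over its probe sets of -0.95 (called under all but 3 of 13 alternatives, adjusted p from 0.00111 to 1). The Y-linked Uty (0.05 ± 0.83) and Usp9y (-1.61 ± 0.45) were not called.

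Ribosomal protein genes served as a reference for abundant transcripts. Of 48, 44 were called (91.7%, 100th percentile; 44 adjusted over the list alone), with Rps3a1 (8.46 ± 0.14), Rps7 (8.42 ± 0.23) and Rpl6 (8.33 ± 0.15) highest. Rps16, part of every ribosome, read -6.20 ± 0.78 on its only probe set, so a probe set without signal does not show that a transcript is missing. Rpl3l, a muscle paralogue, was also not called (-3.65 ± 1.18). Without probe sets that can match several transcripts, 20 ribosomal genes were called. The 10 non-ribosomal genes of highest signal, from Col3a1 (8.60 ± 0.21) to Tsc22d1 (8.41 ± 0.22), were Col3a1, Hmgn1, Hspa8, Eef1a1, Nme2, Actg1, Akr1a1, Tpt1, Ctnnb1 and Tsc22d1. Without probe sets that can match several transcripts, Tpt1 read -2.82 and Hmgn1 0.23 (adjusted p = 0.555, the highest of 13 alternatives, with 7.33e-49 the lowest), and neither was called.

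The pools differed in cell type genes. On array 3 endothelial genes were higher than on both other arrays in 14 of 16 called members, with a median deviation of 0.60, and macrophage genes in 15 of 16, with 0.58; both lay at the 100th percentile of matched lists. Tek had signals of 2589, 3063 and 12518 on arrays 1, 2 and 3, and Mrc1 4691, 5627 and 13723. The signals themselves are not relative to the array's median gene, and macrophage genes rose unevenly. Csf1r had 15761, 13610 and 16341, and C1qa 1616, 1240 and 1539. Nephron progenitor genes deviated by 0.57 on array 3 (99.98th percentile). Of 7 called members 5 were higher there than on both other arrays, such as Itga8 at 8325, 8817 and 17451, and 2 were lower, Sall1 (6408, 8956 and 4324) and Uncx (2857, 1802 and 799). Podocyte transcription factors deviated by -0.55 (0th percentile), podocyte signals by -0.48, early nephron genes by -0.40 and foot process genes by -0.38, the last lower than on both other arrays in 13 of 16 members. Wt1 had signals of 20758, 27556 and 8294. The slit diaphragm list (-0.07), the basement membrane list (-0.12) and the stromal list (0.10) lay within the range of matched lists on array 3. Of the sex-linked genes, Xist was highest on array 3, with signals of 7164, 8103 and 20207 on arrays 1, 2 and 3, and Kdm5d lowest, with 509, 418 and 222. Eif2s3y was lowest there too, with signals of 2869, 2530 and 2027. Above the background level Eif2s3y stood at 3.79, 3.84 and 3.79. That level was itself lowest on array 3, at 147, but its bootstrap intervals overlap between the arrays. The Y-linked Uty (195, 109 and 283) and Usp9y (57.33, 47.67 and 69.05) were highest on array 3, but neither was called. The called members of the sex-linked list deviated by -0.25 on array 3 (12.1th percentile).

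Lists also deviated on arrays 1 and 2. Deviations are taken from a gene's mean over the 3 arrays, so a shift on array 3 forces opposite ones elsewhere. For endothelial, macrophage and nephron progenitor genes and podocyte transcription factors, arrays 1 and 2 both deviated opposite to array 3. Arrays 1 and 2 differed from each other in podocyte signals (-0.02 and 0.45) and foot process genes (0.002 and 0.37). On array 2 podocyte signals (0.45), foot process genes (0.37) and podocyte transcription factors (0.35) were high, and endothelial (-0.43) and macrophage genes (-0.33) low, all outside the central 95% of matched lists. Array 2 also had the lowest signal of the 18S ribosomal RNA control (15127, against 41364 on array 1 and 31866 on array 3, and 1324 against 7227 and 4542 at its 5' end) and the highest ratios of 3' to 5' signal. Whether RNA quality plays a part in the shifts of array 2 was not tested. On array 1 early nephron genes (0.31) and podocyte transcription factors (0.19) were high and nephron progenitor genes (-0.34), endothelial genes (-0.31) and macrophage genes (-0.19) low. Of 20 lists with at least 3 called members, 7, 9 and 8 lay outside that range on arrays 1, 2 and 3, where 1 per array is the chance number for unrelated genes. The 3 counts are not independent, since the same list can enter with opposite signs on different arrays. The spread between arrays exceeded that of matched lists for 11 lists, and for 5 without array 3. Lists of cell state were among those outside the central 95% on an array. Ribosomal genes deviated by 0.08, 0.11 and -0.19 on arrays 1, 2 and 3 (100th, 89.1th and 0th percentile), and 35 of 44 were lower on array 3 than on both other arrays. Under 4 alternatives, quantile normalization among them, their array 3 shift lay between -0.20 and -0.06. These genes are bright, and the highest signal of an array was also lowest on array 3 (72651, 78422 and 63186). The matched lists had like mean signal, so the percentile already compares genes of like brightness. Whether the lower top of the signal range plays a part beyond that was not tested separately. Proliferation genes deviated by 0.12, -0.10 and -0.06 (99.96th, 0.23th and 24.1th percentile) and immediate early genes by -0.06, 0.19 and -0.10 (17.8th, 99.8th and 10.1th percentile). Nephron progenitor genes (-0.25) and stromal genes (-0.11) were the other lists outside the range on array 2.

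**Figure D2:**
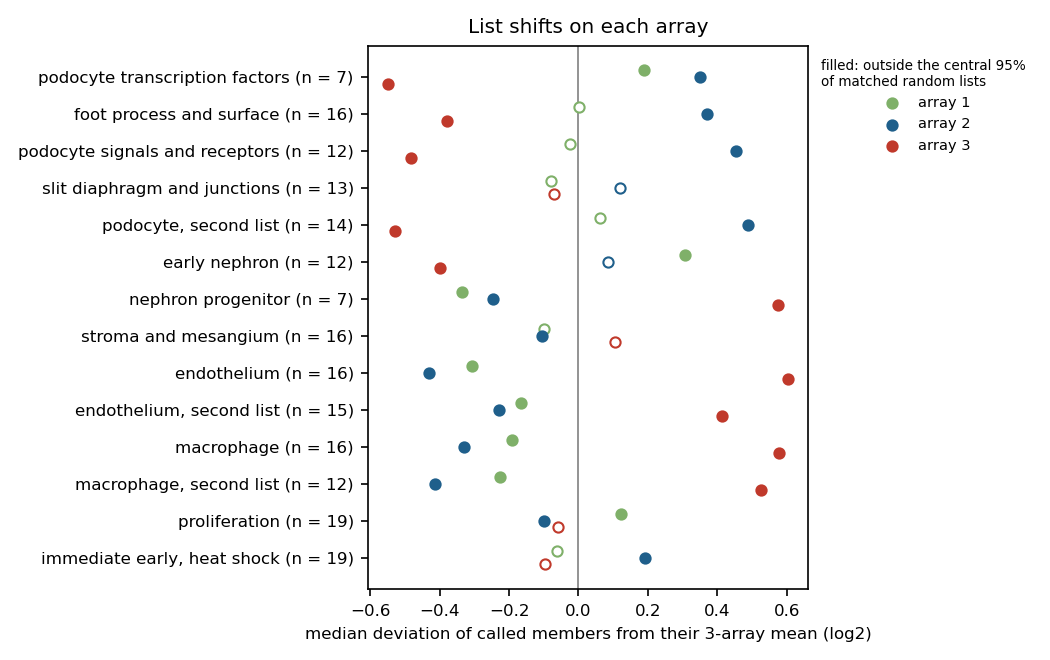
Median deviation of the called members of a list from their mean over the 3 arrays (log2, horizontal axis), for each array (colours) and list (rows, n is the number of called members); filled points lie outside the central 95% of matched random lists. On array 3 endothelial (0.60) and macrophage genes (0.58) lie to the right and podocyte transcription factors (-0.55) to the left.

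Single genes also varied between the arrays. Among the called probe sets 3294 (17.6%) differed by over 2-fold between the highest and lowest array; between pairs of arrays this was 1778 without array 1, 1669 without array 2 and 978 without array 3. The largest range belonged to the glypican gene Gpc3, with signals of 3349, 541 and 11597 on arrays 1, 2 and 3 (a log2 range of 4.42). The nuclear RNA Malat1 followed, with 23549, 1788 and 11758, but another of its 7 probe sets stood at 5.09, 6.02 and 5.04 above background. Gdnf, the growth factor that drives ureteric branching, had 474, 1223 and 3342, the imprinted antisense RNA Kcnq1ot1 2613, 757 and 5617, and the endothelial lectin gene Clec1a 232, 659 and 1825. The others of the 10 were Galnt7, Dner, AW011738, Zfp606 and Bcat1, with ranges from 2.89 (Bcat1) to 3.44 (Galnt7). Galnt7 (1.51, adjusted p = 0.0676) and Dner (0.78, adjusted p = 0.0752) were not called without array 3, nor was AW011738 without array 1 (0.38, adjusted p = 0.44). Of 13 alternatives, AW011738 lost its call under 6 (adjusted p from 0.00282 to 0.723), Galnt7, Zfp606 and Bcat1 each under 3 (highest adjusted p 0.0817, 0.0678 and 1), Dner and Clec1a each under 2 (0.0881 and 0.903) and Kcnq1ot1 under 1 (0.202). Bcat1 had a mean over its probe sets of -0.56.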

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

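No test in this part was chosen after the result was seen. Among probe sets that no gene list or named gene used, because they carry no single gene symbol here, 1839 of 10092 (18.2%) gave signal above background by limma. That is a signal in data outside the gene-level results. These probe sets are unnamed here, which does not mean that they lack a gene. Mafb and Nphs2 have no named probe set here, and whether any of the 1839 belongs to them was not tested. The arrays form 1 group, so no difference between groups was tested.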

How the results depend on the processing

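Tests without keratin-associated proteins in the background list, and the list shifts recomputed on array 3, were chosen only after the results were seen. No paired analysis was possible because there is only 1 group. The number of genes above background ranged from 8689 with the mean over probe sets to 11556 with the 40th percentile as background, and of the 10599 genes 10593 were also called after quantile normalization, 9404 at the 99th percentile and 8674 with the mean over probe sets. Of 325 recomputed list counts 297 stayed within 1.5 times the reported count, and the 28 others concerned small counts or ribosomal genes. The spread between arrays is largest at low signal: the median SD was 1.16 (log2) in the dimmest of 4 equal groups of probe sets and 0.25 in the brightest. Calls of bright genes changed too, where another probe set was taken, and the cause was not tested for the values below. Without array 2 the fit pooled the variances almost wholly (405 prior degrees of freedom, against 6.04), so its calls take little account of a probe set's own spread. Its adjusted p-values enter the ranges given over the alternatives and are not comparable with those of the main fit. The lowest values of those ranges are therefore no measure of stronger evidence. Of the array 3 list shifts all 76 recomputed values moved by less than the members' median SD across the arrays. That SD includes the shift itself, so the limit is loose. The hypoxia list, for example, ran from -0.07 to 0.25. None of the lists outside the matched range on array 3 changed sign.

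Loop and distal tubule genes numbered 2 in place of 1 at the 90th percentile, with the 40th percentile of all probe sets, with a call on all arrays and without keratin-associated proteins, and 1 to 2 with an array left out. Ureteric genes numbered 2 in place of 4 at the 99th percentile and with the mean over probe sets, and 2 to 4 with an array left out. Erythroid genes numbered 1 in place of 2 after quantile normalization, with the mean over probe sets, without the variance trend and with a call on all arrays, 0 at the 99th percentile and without _s_at, _x_at and _a_at probe sets, and 0 to 2 with an array left out. Neural crest genes numbered 1 in place of 2 at the 99th percentile, without those probe sets and without the trend, 0 with the mean over probe sets, and 1 to 2 with an array left out. Adrenal and liver genes numbered 1 in place of 0 with the pseudocount, at the 90th and 99th percentiles and with a call on all arrays, 3 with the 40th percentile, and 0 to 2 with an array left out. Ribosomal genes numbered 20 in place of 44 without _s_at, _x_at and _a_at probe sets, where fewer probe sets were tested. Probe sets over 2-fold apart numbered 20888 in place of 3294 with no filter on dim probe sets, and 978 to 1778 with an array left out, where a pair has a smaller range by construction. Lists with a wide spread numbered 5 in place of 11 with the mean over probe sets, 7 without _s_at, _x_at and _a_at probe sets, and 5 to 9 with an array left out.

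Of 134 named genes, 23 lost a call under at least 1 alternative and 5 gained one. Without _s_at, _x_at and _a_at probe sets only 114 of them could be examined. The others, among them Wt1, Tjp1 and Adgre1, had no probe set left and so could not lose a call there. Over all alternatives 53 values lost their call, 11 of them with a change of sign, 8 gained a call and 1661 stayed called or uncalled as before. With the mean over probe sets Col4a4 was -1.13, Hnf4a -0.35, Calb1 -0.26, Slc4a1 -1.01, Kdm5d -0.95 and Bcat1 -0.56. Without _s_at, _x_at and _a_at probe sets Prkci was -0.13, Hnf4a -0.71, Acta2 -0.16 and Tpt1 -2.82. At the 99th percentile Alas2 was -0.079. Probe sets of a gene differed in their call for 4795 of 9010 genes with several, so the probe set chosen matters there.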

Other observations

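The tests of stroma against other cell types, of stromal genes by kind of probe set, of tubule genes, of single probe sets for Afp and Alb and of abundant liver transcripts were chosen only after the results were seen, as were the genes Afp, Alb, Hbb-y, Ttr, Apob and Rbp4 and the gene lists of the next paragraph. The further macrophage, endothelial, podocyte and liver lists were drawn up after the differences of array 3 were seen and before their own values were.

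Of the genes controlled by imprinting 10 of 13 were called, a share within the range of matched lists (76.9th percentile). Their median of 6.30 above background (log2) lay at the 100th percentile, but signals of different probes do not rank transcripts by abundance. The called ones deviated by 0.18 on array 3 (99.7th percentile) and by -0.13 on array 2 (0.04th percentile). Genes of BMP and TGF-beta signalling were called in 19 of 22 cases (99.4th percentile), and genes of retinoic acid synthesis and response in 9 of 12 (97.9th percentile). Mesothelial genes were called in 7 of 11 cases (90.5th percentile). The called ones deviated by 0.56 on array 1 (100th percentile) and by 0.02 on array 3, but all 11 by 0.07 on array 1 (66.9th percentile). Nuclear long RNAs were called in 11 of 13 cases (71.98th percentile) and as a list did not deviate outside the matched range on any array, although Malat1 ranged from 23549 on array 1 to 1788 on array 2 on the probe set of highest signal.

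Erythroid and liver transcripts also varied between the pools, untested. The embryonic globin gene Hbb-y had signals of 19.3, 1525 and 4621 on arrays 1, 2 and 3, and was not called (adjusted p = 0.291), on its probe set of highest signal. Another of its 3 probe sets moved alike, and the last stood at -3.91, -4.43 and 0.46 above background. The liver and yolk sac genes Afp (304, 199 and 7308; adjusted p = 0.0562) and Alb (110, 196 and 4152; adjusted p = 0.199) were high on array 3. Over all measured members, the erythroid list deviated by 0.51 on array 3 (97.98th percentile) and by -0.78 on array 1, and the adrenal and liver list by 1.62 on array 3 (100th percentile).

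For the high endothelial and macrophage genes and low podocyte genes of array 3, scaling between arrays was argued against as the whole cause, since after quantile normalization the 2 sides still differed by 0.93 against 0.98 as deposited. A lower podocyte share that raised every other cell type alike was also examined. Relative to macrophage and endothelial genes, stromal genes of like signal deviated by -0.50 (95% bootstrap interval -0.72 to -0.24, over 10 and 32 genes). The interval resamples genes of 1 array and not pools. Podocytes may make the stromal transcripts themselves, which would keep these from rising, so the value does not decide the question. A candidate explanation that met its prediction is more macrophages and endothelial cells and fewer podocytes in that pool. Lists of genes not looked at before moved likewise: further macrophage genes deviated by 0.53, endothelial genes by 0.41 and podocyte genes by -0.53. These lists had 12, 15 and 14 called members of 16, 16 and 15. They are further markers of the same cell types, drawn up after the shifts were seen. Genes of a cell type vary together, so a difference in podocyte maturity could also move podocyte genes this way. The result therefore does not establish a difference in cell numbers. Macrophages make Mafb, so the sort may not remove them, whereas a GFP gate would remove most endothelial cells, and their lists share 0 genes with the podocyte lists. The candidate leaves uncovered on array 3 the slit diaphragm list (-0.07, 25.2th percentile), ribosomal genes (-0.19, 0th), nephron progenitor genes (0.57), early nephron genes (-0.40) and the high Xist. The slit diaphragm list was split, however. Of its 13 called members, 6 were lower on array 3 than on both other arrays and 4 were higher. Nphs1 had signals of 633, 1048 and 428 on arrays 1, 2 and 3, and Cd2ap 15722, 8466 and 18815. Its median therefore does not speak for each member. The rise within the macrophage list was also uneven. Mrc1 had signals of 4691, 5627 and 13723 on arrays 1, 2 and 3, but Csf1r 15761, 13610 and 16341. A difference in podocyte maturity or in the sex of the pooled embryos stays open, and neither was tested.

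The stromal genes gave high signals in a population sorted for a podocyte reporter. Probe sets that can match several transcripts were argued against as the only source, since without them 14 of 16 genes were still called, although Acta2 (-0.16) was not. Cross-hybridisation of single probe sets stays open: 15 of 16 were called at the 99th percentile of the background list, but that level rose by 0.72 and the list's median was 6.14, so brightness alone fixed this count. Carry-over of kidney cells through the sort may add to these signals and stays open: 24.2% of tubule and ureteric genes were called, fewer than of stromal genes but more than none, and no unsorted kidney array was analysed here to show which tubule probe sets respond. Expression of these genes in the GFP-positive cells themselves stays open as well, and no biological explanation was tested.

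For Afp and Alb on array 3, a single faulty probe set was argued against, since 4 of their 6 probe sets lay over 2 (log2) above both other arrays. RNA of liver or yolk sac endoderm in that pool is a possible explanation that stays open. Over 16 further liver genes the deviation there was 0.39 (98.5th percentile), but 15 of them were not called and Rbp4, the called one, was not highest on array 3 (signals of 282, 592 and 483), so this shift is weak support. Of the abundant liver transcripts Apoa1, Ahsg, Ttr and Apob, 1 of 4 lay above background on array 3. Ttr stood at 0.68, Apoa1 at -1.28, Ahsg at -0.65 and Apob at -3.75. No other explanation was tested.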
